A study of Mus musculus with 6 samples.

How the data were processed

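RNA sequencing of Tri-PyMT cells gave 6 samples in 3 groups of 2, namely untreated RFP+ cells, untreated GFP+ cells, and GFP+ cells from cultures with 4 µM 4-hydroperoxy-cyclophosphamide (CTX) for 7 days. The deposited table holds FPKM values (fragments scaled to transcript length and to mapped fragments) made by the authors, with 30743 features and 1 value per sample. Per the submitters' processing notes the tools were CASAVA 1.8.2, FastQC, TopHat, Cufflinks and HTSeq with the mm9 genome build, and their order and settings were not stated. Column sums of the FPKM differed between samples. The most abundant feature held 24.0% to 30.2% of the sum of a sample, and features named only by an accession held 40.4% to 46.2%. Read totals were not given in the sources used here, so no counting error is attached to a value.

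Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances, an intensity trend and all 6 samples in 1 model (3 residual degrees of freedom). Genes with an FPKM of at least 1 in at least 2 samples were tested, 13080 in all, of which 12252 matched the RefSeq gene table of the mouse by name and 11670 were protein-coding there. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 in each comparison. The deposited FPKM were used without further scaling, and each result was also computed after median-ratio scaling and after quantile normalization. The 3 comparisons were untreated GFP+ minus RFP+, CTX-treated minus untreated GFP+, and CTX-treated GFP+ minus RFP+ cells. Untreated GFP+ cells enter 2 of them, so these are not independent.

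The lists, 26 for biology and 8 as sample checks, the tests, the comparisons and the rule for naming genes were chosen before the data were examined. Lists with fewer than 3 measured members were not tested, which left 32 lists and 96 tests, adjusted together. Camera compared each list with all other genes at a preset correlation of 0.01, and was repeated with a correlation estimated from these samples. Of the 96 tests, 48 passed at the preset correlation and 0 with the estimated one (3 at an unadjusted p under 0.05, all in untreated GFP+ minus RFP+, and a lowest adjusted p of 0.787). Fry, which tests whether a list moves on balance 1 way, passed in 10. These were the epithelial and luminal lists in untreated GFP+ minus RFP+, and the glutathione, NRF2 and aldehyde dehydrogenase lists in CTX-treated minus untreated GFP+. In CTX-treated GFP+ minus RFP+ they were the glutathione, NRF2, aldehyde dehydrogenase, luminal and stromal fibroblast lists. No other list test passed in fry. Beside the count of members past the threshold over all genes stands the count adjusted over the list alone. The endothelial list had 3 measured members and passed in none of the 3 comparisons in camera (adjusted p = 0.116, 0.951 and 0.464).

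The genes named were, for each of the first 2 comparisons, the 8 largest changes each way among genes past the threshold with a mean FPKM of at least 10 in the higher group and replicates that did not overlap, up to 3 members of each list, and a panel of genes of interest. Most of the largest changes in the comparisons with CTX-treated cells were short RNA genes. Between the untreated populations Mir671, Snora61 and Mir3101 led by size, and the others were protein-coding. The same rule was therefore also applied to protein-coding genes, a choice made after the data were seen. For the last comparison the rule took 5 genes each way. List members that passed only after median-ratio scaling were also named, likewise after the data were seen. Genes outside the rule, namely Actr3 and single genes under other observations, were chosen after their values were seen.

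The procedure was tested on simulated data with the means and spreads of these genes, with 100 of 13080 genes changed by 1 log2 unit and 100 by 2, in equal numbers up and down. In the first comparison 31% of changes of 1 log2 unit and 97% of changes of 2 units were recovered, in the second 32% and 94%, and in the third 33% and 94%. Of the calls, 14 of 142, 6 of 132 and 17 of 144 were false. The simulation gave every sample of a gene the same spread, which the real groups did not have.

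The alternatives were other pseudocounts, other filters, both scalings, models without the trend or with robust moderation, models of the 4 samples compared, a replicate covariate, a minimum change, and leaving out each sample in turn. Averaging the CTX pair, combining scaling with that or with leaving out untreated GFP+ replicate 1, and leaving out accession-named and short RNA features were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

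The fold column of the table held only division errors and was not used. Spreadsheet software had turned 25 symbols into dates, and these were left as they stood and not named. Features named only by an accession numbered 7579 and were kept in the tests but not named. Between 63 and 99 features per sample were listed at 0 while above 20 FPKM in another sample, including Actr3, at 0 and 92.4 FPKM in the CTX replicates, so an isolated 0 in 1 replicate was not read as absence. No coordinates are given, because the values were made on mm9 and the annotation at hand was of a later build. Counts of reads were not available, so models for counts were not used.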

Results

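Gene expression was measured by RNA sequencing in Tri-PyMT cells, a mouse mammary tumour line that carries a lineage tracer for epithelial-mesenchymal transition (EMT), the loss of epithelial and gain of mesenchymal features. Cells that have not switched on a mesenchymal promoter fluoresce red (RFP+, non-EMT per the labels). Cells that have done so fluoresce green (GFP+, EMT per the labels). The 6 samples formed 3 groups of 2, namely untreated RFP+ cells, untreated GFP+ cells, and GFP+ cells from cultures kept for 7 days with 4 µM 4-hydroperoxy-cyclophosphamide (CTX), a form of the DNA-alkylating drug cyclophosphamide that needs no activation in the liver. The cells had been sorted by flow cytometry before RNA extraction. The labels do not say whether the samples of a group came from separate cultures, so each p-value measures only the spread between these samples, which may be technical.

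Expression was given as FPKM, and read totals per sample were not given in the sources used here. Between 11543 and 12866 genes per sample reached an FPKM of 1. Untreated GFP+ replicate 1 had lower values for most genes than the other samples, with a median-ratio size factor of -0.43 on the log2 scale against 0.03 to 0.15 for the others. Each comparison is therefore given for the FPKM as deposited and after median-ratio scaling. The CTX replicates lay far closer together than the other pairs, with a robust SD of the log2 ratio between replicates of 0.0545, against 0.268 for RFP+ and 0.318 for untreated GFP+ cells. The 3 groups shared one estimate of the spread. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and levels are means ± SD (n = 2).

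The comparison of untreated GFP+ with untreated RFP+ cells asked how EMT cells differed from non-EMT cells without drug. Genes of epithelial junctions and keratins were lower in GFP+ cells. Of 29 measured members, 21 fell, 0 rose and 8 did not pass (29 fell when adjusted over the list alone), with a list median of -1.81. E-cadherin (Cdh1), the main adhesion molecule of epithelial junctions, was at 14.1 ± 5.05 against 70.7 ± 12.4 FPKM and fell by 2.28 (SE 0.26, adjusted p = 0.0161). The epithelial adhesion molecule Epcam fell by 2.03 (SE 0.30, adjusted p = 0.0262). The epithelial splicing regulator Esrp1 fell by 2.24 (SE 0.20, adjusted p = 0.0102) and the tricellular junction component Lsr fell by 2.31 (SE 0.19, adjusted p = 0.0102). The list lay below other genes in camera's test with a preset correlation (adjusted p = 8.28e-28; adjusted p = 0.787 with an estimated correlation). After scaling its median was -1.59 and 22 members fell.

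Luminal mammary genes were also lower, with 7 of 18 members falling (11 when adjusted over the list alone, after scaling 7 fell), a median of -1.26 and an adjusted p of 2.13e-06 in camera (adjusted p = 0.787 with an estimated correlation). The milk-serum family member Wfdc18 was at 34.4 ± 3.47 against 191 ± 40.5 FPKM and fell by 2.43 (SE 0.20, adjusted p = 0.0102). The transcriptional co-regulator Cited1 fell by 1.65 (SE 0.15, adjusted p = 0.0102) and the luminal keratin Krt19 fell by 1.63 (SE 0.19, adjusted p = 0.0161). Among basal mammary genes, 1 of 16 fell (2 rose and 4 fell when adjusted over the list alone, after scaling 1 rose and 2 fell). The 1 as deposited was the basal keratin Krt14, at 86.9 ± 25.4 against 207 ± 8.52 FPKM (fell by 1.28, SE 0.23, adjusted p = 0.0490). Krt5 was at 13.4 ± 4.31 against 5.39 ± 1.10 FPKM and rose only after scaling (log2 change 1.39, adjusted p = 0.0220 scaled and 0.0904 as deposited). The protein-coding genes with the largest decreases, apart from those named, included the growth factor Fgf7 (fell by 2.45, SE 0.20, adjusted p = 0.0102), the potassium channel Kcnk1 (fell by 2.33, SE 0.21, adjusted p = 0.0102) and Tmem54 (fell by 2.44, SE 0.20, adjusted p = 0.0102).

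Mesenchymal and matrix genes lay higher in GFP+ cells as lists, while few single members passed. The proteoglycan decorin (Dcn) was at 41.9 ± 16.3 against 9.82 ± 3.54 FPKM and rose by 1.97 (SE 0.32, adjusted p = 0.0362). The secreted serpin Serpinf1 rose by 1.39 (SE 0.17, adjusted p = 0.0161) and the chemokine Cxcl12 by 1.28 (SE 0.18, adjusted p = 0.0227). Neither Serpinf1 nor Cxcl12 passed in a model of only the 4 untreated samples. Of 21 mesenchymal genes 1 rose (10 when adjusted over the list alone). Of 28 collagen and matrix glycoprotein genes 2 rose (12 when adjusted over the list alone). Their medians were 0.54 and 0.58, and camera placed both lists above other genes (adjusted p = 2.85e-16 and 1.21e-22; adjusted p = 0.787 for both with an estimated correlation). After scaling 6 mesenchymal and 7 matrix genes rose, among them the PDGF receptor Pdgfra (log2 change 1.28, adjusted p = 0.0154 scaled and 0.0877 as deposited) and the collagen VI chain Col6a2 (log2 change 1.43, adjusted p = 0.0309 scaled and 0.122 as deposited). Stromal fibroblast markers, included as a check for other cells, overlapped these lists, and 2 of 9 rose (4 when adjusted over the list alone, after scaling 4 rose; camera adjusted p = 6.42e-09, adjusted p = 0.787 with an estimated correlation).

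Several widely used EMT markers did not pass the test. S100a4, whose promoter is a common choice for tracing mesenchymal cells, was at 1769 ± 22.2 against 983 ± 394 FPKM, with 1261 and 704 FPKM in the 2 RFP+ samples (log2 change 0.91, SE 0.31, adjusted p = 0.222 as deposited, 1.18 and 0.197 scaled). Vimentin (Vim) was at 1075 ± 174 against 648 ± 33.4 FPKM (log2 change 0.72, adjusted p = 0.182). N-cadherin (Cdh2) was at 21.3 ± 1.05 against 13.4 ± 3.31 FPKM (log2 change 0.65, adjusted p = 0.198) and fibronectin (Fn1) at 733 ± 322 against 588 ± 61.5 FPKM (log2 change 0.25, adjusted p = 0.666). Vim, Cdh2 and Fn1 are given as deposited, where the median over all genes was -0.24. Of 12 EMT transcription factors none passed (2 had an unadjusted p under 0.05 in limma). Camera placed the list above other genes (adjusted p = 8.41e-04; adjusted p = 0.843 with an estimated correlation). After scaling 1 rose, Zeb1 (log2 change 0.94, adjusted p = 0.0192 scaled and 0.198 as deposited).

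**Figure D1:**
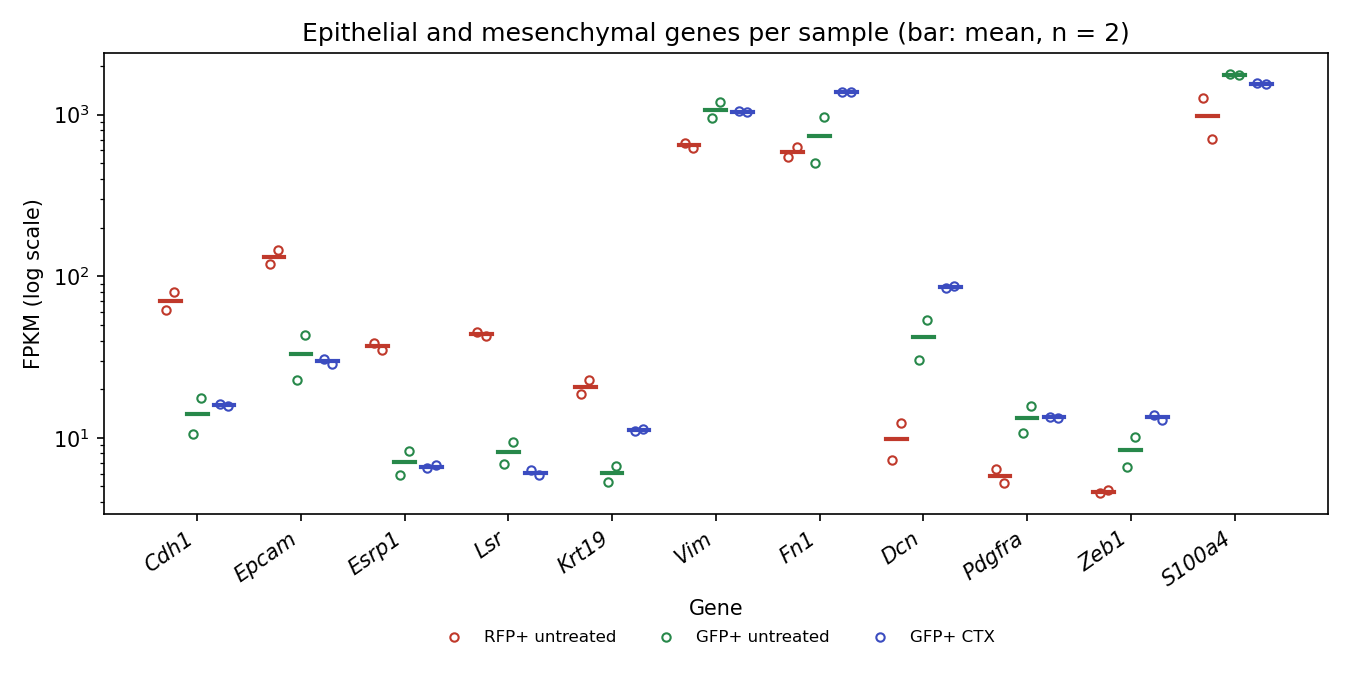
FPKM (log axis) of 5 epithelial genes and 6 mesenchymal or EMT-related genes in each of the 6 samples, with each point a sample and each bar the mean of a group of 2. Cdh1 lay between 62.0 and 79.5 in RFP+ samples and between 10.5 and 17.7 in untreated GFP+ samples, and S100a4 was at 704 FPKM or more in every sample.

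As deposited, no gene of the drug-handling or DNA repair lists passed between the untreated populations. None of 17 aldehyde dehydrogenase genes, 18 cytochrome P450 genes, 31 glutathione genes, 24 ABC transporter genes or 34 DNA repair genes passed in limma (unadjusted p under 0.05 for 2, 2, 6, 4 and 5). When adjusted over the list alone 1 cytochrome P450 gene and 2 glutathione genes fell and none of the other 3 lists had a member past the threshold. After scaling 3 of these genes passed. The glutathione transferase Gsta4 (log2 change -1.03, adjusted p = 0.0455 scaled and 0.0563 as deposited) and the cytochrome Cyp2f2 (-0.74, 0.0356 and 0.0647) fell, and the glutathione peroxidase Gpx8 rose (0.58, 0.0455 and 0.414). Aldh1a1, an aldehyde dehydrogenase that detoxifies cyclophosphamide, was at 0.481 ± 0.285 against 0.207 ± 0.0377 FPKM (log2 change 0.28, adjusted p = 0.419). The p53 target Cdkn1a was at 32.0 ± 33.7 against 37.6 ± 29.8 FPKM (log2 change -0.50, adjusted p = 0.755). None of 38 mitosis and replication genes passed (3 at an unadjusted p under 0.05). The proliferation marker Mki67 was at 46.7 ± 17.3 against 49.6 ± 2.45 FPKM (log2 change -0.13 as deposited and 0.13 scaled, adjusted p = 0.779 and 0.759). Of 27 cytokines and chemokines 1 rose and 1 fell (3 and 2 when adjusted over the list alone, after scaling 2 rose and 1 fell). As deposited these were Cxcl12 and Cxcl16 (fell by 1.66, SE 0.28, adjusted p = 0.0420). Of 17 stem and progenitor genes 1 fell (3 when adjusted over the list alone, after scaling 2 fell), as deposited the surface marker Prom1 (fell by 0.92, SE 0.14, adjusted p = 0.0273).

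No member of the p53 target, pro-apoptotic, anti-apoptotic, NRF2, MHC class I, hypoxia, cholesterol synthesis, unfolded protein response, TGF-beta, YAP target or matrix protease lists passed in limma as deposited (4, 3, 0, 3, 0, 2, 0, 2, 2, 2 and 4 members at an unadjusted p under 0.05), nor did any when adjusted over the list alone. The same held for the interferon-stimulated, EMT transcription factor, mitosis, histone and ribosomal protein lists, with 0, 2, 3, 8 and 10 members at an unadjusted p under 0.05. After scaling the TGF-beta gene Ltbp1 fell (log2 change -0.74, adjusted p = 0.0364 scaled and 0.103 as deposited), and the matrix protease Mmp2 rose (0.72, 0.0330 and 0.211), as did Zeb1 as given above. When adjusted over the list alone after scaling, 2 TGF-beta genes, 3 matrix protease genes and 2 EMT transcription factors rose and 1 TGF-beta gene fell. Camera placed the interferon-stimulated, MHC class I, hypoxia, cytokine, cytochrome P450 and matrix protease lists above other genes (adjusted p = 2.64e-04, 0.0408, 0.0140, 0.0107, 0.00401 and 2.64e-04), although their medians were 0.04, -0.05, -0.16, -0.13, 0.02 and -0.02. After scaling the interferon-stimulated, MHC class I and cytokine lists no longer passed (adjusted p = 0.129, 0.102, 0.0104, 0.232, 0.0215 and 0.00389 in the same order), nor after quantile normalization (adjusted p = 0.178, 0.127 and 0.279 for these 3). With an estimated correlation none passed (adjusted p = 0.843, 0.850, 0.843, 0.843, 0.843 and 0.843 in the same order). Replication-dependent histone genes, most of whose mRNAs lack a poly(A) tail, had a median of 1.23 with 0 of 25 passing (8 at an unadjusted p under 0.05; camera adjusted p = 2.22e-20, adjusted p = 0.787 with an estimated correlation). They differed by -2.22 between untreated GFP+ replicates 2 and 1 after scaling. Ribosomal protein genes had a median of -0.50 and 0 of 50 passed (10 at an unadjusted p under 0.05; camera adjusted p = 1.43e-04, adjusted p = 0.843 with an estimated correlation).

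In total, limma with Benjamini-Hochberg adjustment placed 15 genes higher and 233 lower in GFP+ cells among 13080 tested, against 133 and 257 after scaling and 128 and 240 after quantile normalization. Of the genes called as deposited, 11 and 200 were also called after scaling. The median over all tested genes was -0.24 as deposited and -0.01 after scaling, so deposited decreases include a shift of that size. Higher genes made up 6.05% of calls as deposited and 34.1% after scaling. By size alone the list of changes was led by short RNA genes such as Snora61 (328 and 653 FPKM in RFP+ samples, listed at 0 in both untreated GFP+ samples), whose FPKM is unreliable because the transcripts are shorter than most sequenced fragments. The count of lower genes became 3 or 1 without RFP+ replicate 1 or 2, 91 or 4576 without untreated GFP+ replicate 1 or 2, and 128 or 130 without CTX replicate 1 or 2. The count of higher genes became 0, 0, 14, 161, 8 and 8 in the same order (limma, with 262 and 138 at an unadjusted p under 0.05 for the counts of 0). The naming rule and its protein-coding version selected 23 genes past the threshold. Of these 21 passed after scaling, all but Bgn (adjusted p = 0.0605) and Mir671 (0.0680). In limma on only the 4 untreated samples, without the close CTX pair, 17 of the 23 passed (23 at an unadjusted p under 0.05). Those lost were Cxcl12, Cxcl16, Grb14, Krt14, Prom1 and Serpinf1. Of the selected genes 2 passed without RFP+ replicate 1 (Mir3101 and Snora61), and only Snora61 passed without RFP+ replicate 2 or without the filter on low values (unadjusted p under 0.05 for 23, 23 and 23). Of the same genes 12 and 23 passed without untreated GFP+ replicate 1 or 2, and 18 and 18 without CTX replicate 1 or 2. With the CTX pair averaged and values scaled none passed in limma (23 at an unadjusted p under 0.05). Untreated RFP+ and GFP+ replicate 2 differed from replicate 1 in interferon-stimulated genes (median 1.51 and 1.38 after scaling), and none of the 31 members passed between the populations (0 at an unadjusted p under 0.05).

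The comparison of CTX-treated with untreated GFP+ cells asked how EMT cells with the drug differed from those without. The labels give a time in culture only for the CTX samples, so a difference in that time cannot be told from the drug. In pooled cells a change also cannot be told from survival of a part of them. Targets of p53, the transcription factor that responds to DNA damage, rose, with 18 of 27 members passing (20 when adjusted over the list alone, after scaling 14 rose) and a median of 1.60. Between the untreated replicates the p53 targets also differed, by a scaled median of 0.62 in RFP+ and 0.81 in GFP+ cells (replicate 2 minus 1), against a scaled CTX change of 1.26. The pro-apoptotic gene Pmaip1 went from 1.75 ± 1.54 to 29.9 ± 1.09 FPKM and rose by 3.61 (SE 0.39, adjusted p = 0.00311). The stress cytokine Gdf15 rose by 4.16 (SE 0.54, adjusted p = 0.00558). The cell cycle inhibitor Cdkn1a was at 265 FPKM in both CTX samples and at 8.19 and 55.9 in the untreated samples (log2 change 3.54, SE 0.88, adjusted p = 0.0452 as deposited and 0.0669 scaled). Camera placed the list of p53 targets above other genes (adjusted p = 5.08e-07; adjusted p = 0.843 with an estimated correlation), and it did not pass in fry (adjusted p = 0.133). Of 21 pro-apoptotic genes 8 rose (9 when adjusted over the list alone, after scaling 8 rose and 1 fell), including the death receptor Tnfrsf10b (log2 change 1.40, SE 0.33, adjusted p = 0.0393). The lists overlap, and Bbc3, Fas, Pmaip1 and Tnfrsf10b were counted among the risen p53 targets too. Of 12 anti-apoptotic genes 1 rose (4 when adjusted over the list alone, after scaling 3 rose), the caspase-8 inhibitor Cflar (from 9.76 ± 3.56 to 19.9 ± 1.48 FPKM, SE of the log2 change 0.25, adjusted p = 0.0487). Neither list passed in camera as deposited (adjusted p = 0.0868 and 0.444) or after scaling (adjusted p = 0.0643 and 0.406), and the pro-apoptotic list passed after quantile normalization (adjusted p = 0.0203; adjusted p = 0.843 with an estimated correlation).

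Glutathione genes, NRF2 targets and aldehyde dehydrogenase genes lay above other genes after CTX at the preset correlation of camera, though not at an estimated one. Of 31 glutathione genes 18 rose (23 when adjusted over the list alone, after scaling 13 rose), with a median of 0.99. The glutathione transferase Gsta4 went from 16.7 ± 5.05 to 120.1 ± 1.64 FPKM (log2 change 2.81, SE 0.24, adjusted p = 0.00168). Of 22 targets of NRF2, the transcription factor of the oxidative stress response, 12 rose (18 when adjusted over the list alone, after scaling 10 rose), including heme oxygenase Hmox1 (log2 change 2.37, SE 0.20, adjusted p = 0.00156) and Gclc, which catalyses the rate-limiting step of glutathione synthesis (log2 change 2.40, SE 0.32, adjusted p = 0.00623). Gclc, Gclm, Gsta3 and Slc7a11 were counted among the risen genes of both the glutathione and NRF2 lists. Of 17 aldehyde dehydrogenase genes 9 rose (11 rose and 1 fell when adjusted over the list alone, after scaling 8 rose and 1 fell). Aldh1a1 went from 0.481 ± 0.285 to 4.80 ± 0.530 FPKM (log2 change 1.98, SE 0.18, adjusted p = 0.00210). The far more abundant Aldh3a1 went from 86.7 ± 68.5 to 454 ± 3.67 FPKM (log2 change 2.64, SE 0.67, adjusted p = 0.0484 as deposited and 0.0717 scaled).

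Of 18 cytochrome P450 genes 7 rose (8 when adjusted over the list alone, after scaling 5 rose), led by Cyp1a1 (log2 change 2.36, SE 0.18, adjusted p = 0.00108). Of 24 ABC transporter genes 7 rose (11 when adjusted over the list alone, after scaling 7 rose and 2 fell), including the multidrug transporter Abcb1a (log2 change 1.62, SE 0.19, adjusted p = 0.00394). In camera the glutathione (adjusted p = 7.82e-08), NRF2 (2.15e-07), aldehyde dehydrogenase (0.00150) and ABC transporter (0.0470) lists lay above other genes, and the cytochrome P450 list did not pass as deposited (0.0602). After scaling both the cytochrome P450 and ABC transporter lists passed (adjusted p = 0.0170 and 0.0202), and after quantile normalization neither did (adjusted p = 0.0857 and 0.0719). With an estimated correlation none of the 4 that passed as deposited did so (adjusted p = 0.787 for the first 3 and adjusted p = 0.843 for ABC transporters, and 0.843 for cytochrome P450 genes). Of 34 DNA crosslink and damage repair genes 1 rose and 1 fell (1 each way when adjusted over the list alone, after scaling 1 rose and 9 fell). As deposited these were Mgmt, which removes alkyl groups from guanine (log2 change 1.21, SE 0.19, adjusted p = 0.0122), and the uracil glycosylase Ung (log2 change -1.08, SE 0.19, adjusted p = 0.0160).

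Interferon-stimulated genes had the highest median of the 32 lists tested, 2.19, and all 31 of 31 members had a positive log2 change. The untreated replicates spread widely, with 8 members past the threshold over all genes and 28 when adjusted over the list alone, or 6 and 6 after scaling (camera adjusted p = 6.33e-06; adjusted p = 0.843 with an estimated correlation). The antiviral gene Rsad2 was at 44.7 and 45.8 FPKM with CTX and at 0.828 and 6.30 without (log2 change 3.66, SE 0.74, adjusted p = 0.0252). The GTPase gene Mx1 rose by 3.81 (SE 0.70, adjusted p = 0.0183). In the MHC class I and antigen presentation list 3 of 14 rose (12 when adjusted over the list alone, after scaling 1 rose; camera adjusted p = 0.00835, adjusted p = 0.843 with an estimated correlation), including the immunoproteasome subunit Psmb9 (log2 change 1.56, SE 0.32, adjusted p = 0.0263). Of 27 cytokines and chemokines 12 rose and 1 fell (15 and 1 when adjusted over the list alone, after scaling 10 rose and 2 fell; camera adjusted p = 0.00150, adjusted p = 0.843 with an estimated correlation). The chemokine Ccl5 went from 15.4 ± 6.68 to 177 ± 2.34 FPKM (log2 change 3.50, SE 0.38, adjusted p = 0.00327). The growth factor Csf2 went from 0.212 ± 0.300 to 10.6 ± 1.54 (log2 change 3.27, SE 0.25, adjusted p = 0.00108).

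**Figure D2:**
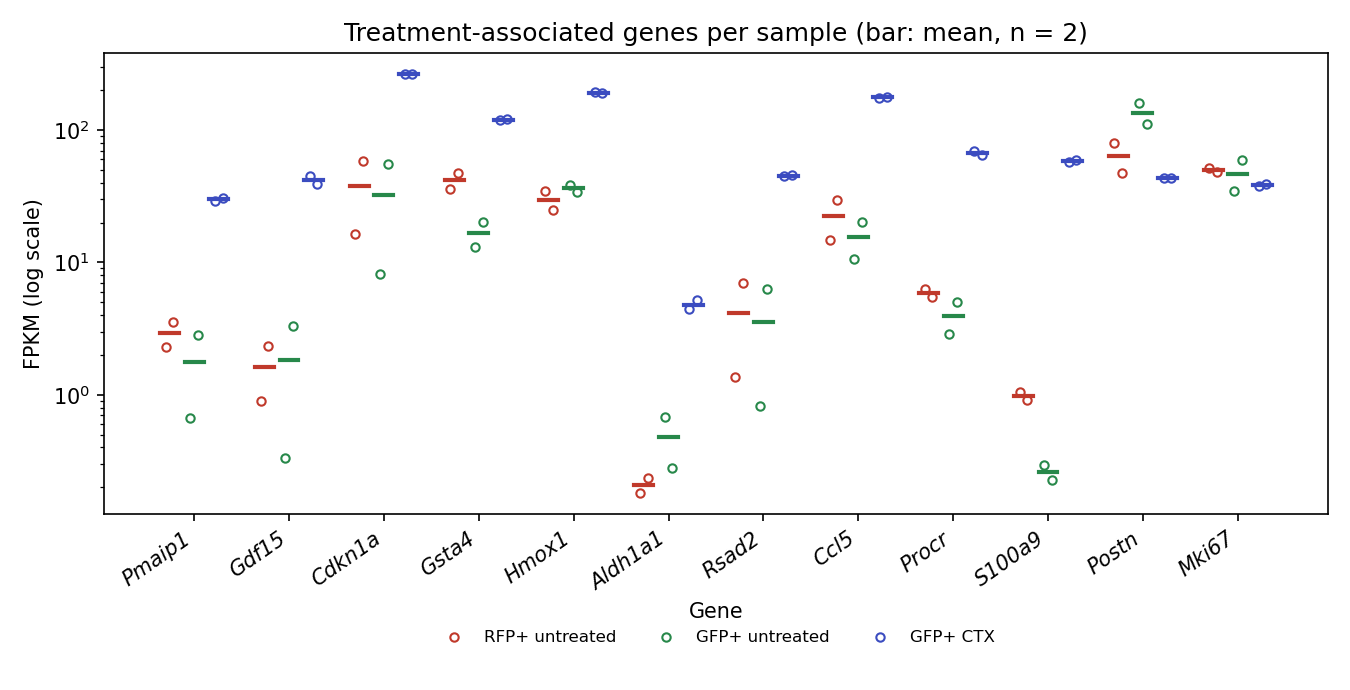
FPKM (log axis) of 12 genes in each of the 6 samples, with each point a sample and each bar the mean of a group of 2. Pmaip1 lay at 29.2 and 30.7 FPKM in the CTX samples and at 2.84 or less in untreated GFP+ samples, and Postn at 43.1 and 43.5 with CTX against 159.6 and 110.4 without.

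Epithelial genes did not pass as a group after CTX. Of 29 members 5 rose (6 when adjusted over the list alone, after scaling 2 rose and 1 fell; camera adjusted p = 0.327), including the tight junction gene Cldn4 (log2 change 2.65, SE 0.48, adjusted p = 0.0176) and the desmosomal gene Dsp (log2 change 1.85, SE 0.27, adjusted p = 0.00923). Cdh1 was at 15.9 ± 0.300 against 14.1 ± 5.05 FPKM (log2 change 0.20 as deposited and -0.13 scaled, adjusted p = 0.645 and 0.609). Epcam was at 29.7 ± 1.33 against 33.0 ± 14.6 FPKM (log2 change -0.08, adjusted p = 0.885). Of 21 mesenchymal genes 2 fell (2 when adjusted over the list alone, after scaling 2 fell; camera adjusted p = 0.0784), the matrix gene Postn (fell by 1.60, SE 0.29, adjusted p = 0.0185) and the PDGF receptor Pdgfrb (fell by 1.09, SE 0.17, adjusted p = 0.0114). S100a4 (log2 change -0.19, adjusted p = 0.720), Vim (-0.04, 0.924), Cdh2 (-0.26, 0.436) and Fn1 (0.98, 0.0959) did not pass. These values and that of Epcam are as deposited, where the median over all genes was 0.25. Of 16 basal mammary genes 4 rose (6 when adjusted over the list alone, after scaling 4 rose; camera adjusted p = 0.103, 0.0176 scaled, 0.00474 after quantile normalization and 0.843 with an estimated correlation), led by the keratin Krt15 (log2 change 2.25, SE 0.21, adjusted p = 0.00222). Of 18 luminal genes 4 rose and 2 fell (4 and 2 when adjusted over the list alone, after scaling 2 rose and 4 fell; camera adjusted p = 0.296). The iron-binding secretory protein Ltf rose (log2 change 2.57, SE 0.41, adjusted p = 0.0121).

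Of 17 stem and progenitor genes 5 rose (6 when adjusted over the list alone, after scaling 5 rose and 2 fell; camera adjusted p = 0.103). The surface receptor Procr went from 3.94 ± 1.52 to 67.2 ± 3.95 FPKM (log2 change 3.82, SE 0.24, adjusted p = 7.66e-04). The surface antigen Ly6a went from 232 ± 42.7 to 1828 ± 50.6 FPKM (log2 change 2.98, SE 0.21, adjusted p = 0.00104). The protein-coding genes with the largest increases included the calgranulin S100a9 (from 0.259 ± 0.0481 to 58.4 ± 1.02 FPKM, log2 change 5.56, SE 0.16, adjusted p = 3.92e-05) and the cornified envelope gene Sprr2h (log2 change 4.56, SE 0.17, adjusted p = 9.02e-05). Stefin A3 (Stfa3) was listed at 0 in both untreated GFP+ samples and at 30.1 and 29.3 FPKM with CTX (adjusted p = 4.40e-05). Among sample checks, 2 of 4 measured leukocyte markers rose (2 when adjusted over the list alone, after scaling 2 rose; camera adjusted p = 0.0623). These were the lysosomal gene Cd68 (log2 change 2.54, SE 0.29, adjusted p = 0.00376) and the lysozyme gene Lyz2 (log2 change 1.16, SE 0.18, adjusted p = 0.0114). Of 9 stromal fibroblast markers 4 rose and 1 fell (5 and 1 when adjusted over the list alone, after scaling 4 rose and 1 fell; camera adjusted p = 0.390). The adipocyte marker Fabp4 went from 7.60 ± 1.98 to 17.1 ± 0.589 FPKM (log2 change 1.10, SE 0.21, adjusted p = 0.0209 as deposited and 0.00981 scaled). Between untreated GFP+ and RFP+ cells it rose only after scaling (log2 change 0.95, adjusted p = 0.0155 scaled and 0.175 as deposited).

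Genes of proliferation and of sterol synthesis lay lower relative to other genes. None of 38 mitosis and replication genes passed as deposited (4 at an unadjusted p under 0.05 in limma), and 12 fell after scaling (24 when adjusted over the list alone). The replication helicase subunit Mcm2 fell only after scaling (log2 change -0.90, adjusted p = 0.00921 scaled, -0.55 and 0.0950 as deposited), as did Mki67 (log2 change -0.57, adjusted p = 0.0451 scaled, -0.22 and 0.608 as deposited). Camera placed the list below other genes as deposited (adjusted p = 9.90e-07; adjusted p = 0.843 with an estimated correlation). Cholesterol synthesis genes had a median of -1.02, with all 22 of 22 negative, and none passed singly, nor when adjusted over the list alone (4 at an unadjusted p under 0.05; camera adjusted p = 3.03e-12, adjusted p = 0.843 with an estimated correlation). Their spread between untreated replicates was as large as the change, with Fdps at 242 and 85.8 FPKM untreated and 56.9 and 55.9 with CTX (log2 change -1.34, adjusted p = 0.204). Of 19 unfolded protein response genes 5 rose (7 when adjusted over the list alone, after scaling 3 rose; camera adjusted p = 0.464), including the transcription factor Ddit3 (log2 change 2.23, SE 0.24, adjusted p = 0.00331). Histone genes (2 of 25 rose, 2 when adjusted over the list alone, after scaling 2 rose) and ribosomal protein genes (0 of 50 passed, 0 at an unadjusted p under 0.05) had medians of -0.51 and -0.20 (camera adjusted p = 0.00803 and 1.17e-09; adjusted p = 0.843 for both with an estimated correlation). The histone list no longer passed after scaling or quantile normalization (adjusted p = 0.748 and 0.714), and the ribosomal list passed in both (adjusted p = 8.40e-06 and 0.00474). The DNA repair list had a median of 0.01 (camera adjusted p = 0.00545; adjusted p = 0.843 with an estimated correlation). In fry the mitosis, cholesterol synthesis, histone, ribosomal protein and DNA repair lists did not pass (adjusted p = 0.742, 0.441, 0.961, 0.649 and 0.969).

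Of the lists not yet described, 3 of 28 matrix genes rose and 2 fell with CTX (3 and 2 when adjusted over the list alone, after scaling 2 rose and 4 fell; camera adjusted p = 0.0876). Elastin (Eln) rose by 1.64 (SE 0.18, adjusted p = 0.00311). Of 21 matrix proteases and inhibitors 5 rose and 1 fell (10 and 2 when adjusted over the list alone, after scaling 4 rose and 2 fell; camera adjusted p = 0.221, 0.0692 scaled, 0.0213 after quantile normalization and 0.916 with an estimated correlation). The protease Adamts1 fell by 1.13 (SE 0.26, adjusted p = 0.0369). Of 26 hypoxia and glycolysis genes 4 rose (10 when adjusted over the list alone, after scaling 4 rose; camera adjusted p = 0.151, 0.114 scaled, 0.00474 after quantile normalization and 0.881 with an estimated correlation), including Ndrg1 (log2 change 2.29, SE 0.31, adjusted p = 0.00674). Of 23 TGF-beta pathway genes 2 rose (1 when adjusted over the list alone; camera adjusted p = 0.472), but after scaling 1 rose and 3 fell (2 and 6 when adjusted over the list alone). Of 18 immediate early and heat shock genes 3 rose (5 rose and 2 fell when adjusted over the list alone, after scaling 3 rose; camera adjusted p = 0.242). None of 12 EMT transcription factors or 18 YAP targets passed in limma as deposited, over all genes or when adjusted over the list alone (4 and 3 at an unadjusted p under 0.05). After scaling the transcription factor genes Sox9 (log2 change -0.96, adjusted p = 0.0187 scaled and 0.170 as deposited) and Tcf4 (-0.73, 0.0304 and 0.192) fell. The YAP target Amotl1 rose (0.62, 0.0408 and 0.0586). When adjusted over the list alone after scaling, 3 transcription factors rose and 3 fell, and of 18 YAP targets none passed in limma (4 at an unadjusted p under 0.05).

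Counted over all genes, limma called 1607 higher and 62 lower with CTX, against 1437 and 1052 after scaling and 1404 and 1477 after quantile normalization, with 1321 higher and 60 lower genes called both as deposited and after median-ratio scaling. The median over all genes was 0.25 as deposited and -0.05 after scaling, so log2 changes are to be read relative to that median. Higher genes made up 96.3% of calls as deposited and 57.7% after scaling. Higher and lower genes numbered 679 and 24 without RFP+ replicate 1, 676 and 24 without RFP+ replicate 2, 1127 and 269 without untreated GFP+ replicate 1, 5653 and 199 without untreated GFP+ replicate 2, 431 and 12 without CTX replicate 1, and 436 and 19 without CTX replicate 2. Because the CTX replicates lay so close together, they were also averaged and counted as 1 sample, a choice made after the data were seen, which left 424 higher and 8 lower genes, or 45 and 0 with scaling as well (1014 lower at an unadjusted p under 0.05 in limma). The naming rule selected 96 genes past the threshold, of which 83 passed after scaling. The 13 others were Aldh3a1, Areg, Ccl2, Cd74, Cdkn1a, Chac1, Cxcl10, Nlrc5, Ovol1, Tgfbr1 and the microRNAs Mir23a, Mir671 and Mir704. Of the same genes 58 and 58 passed without RFP+ replicate 1 or 2, 65 and 90 without untreated GFP+ replicate 1 or 2, 53 and 56 without CTX replicate 1 or 2, and 12 with the CTX pair averaged and values scaled.

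**Figure D3:**
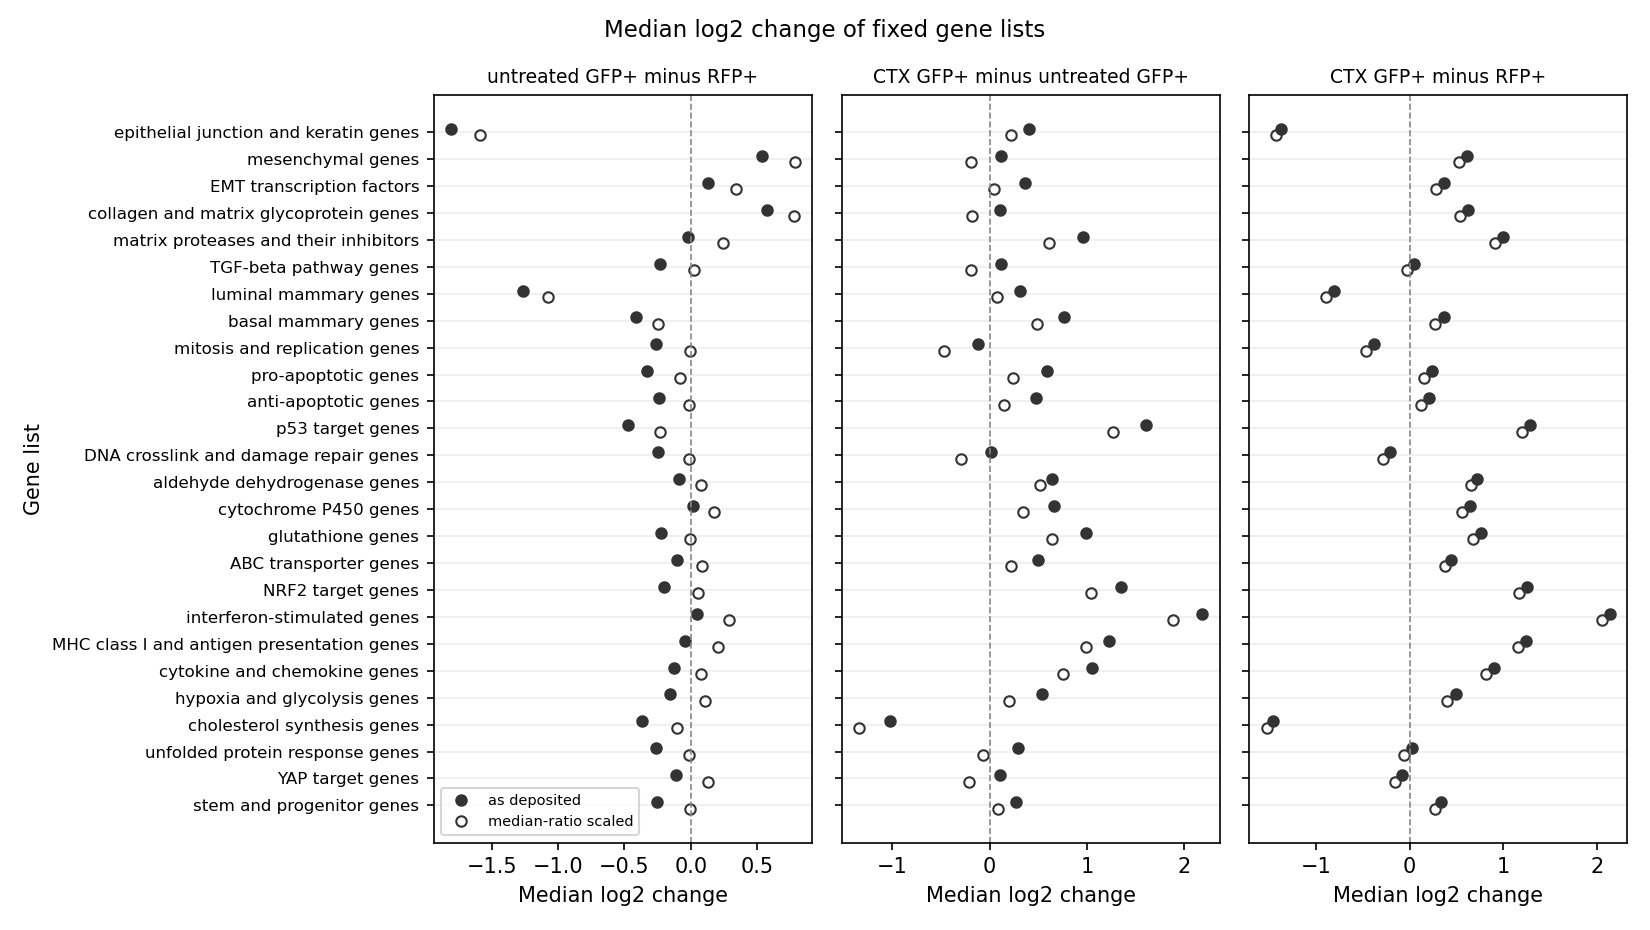
Median log2 change of 26 fixed gene lists in the 3 comparisons, as deposited (filled points) and after median-ratio scaling (open points), with a dashed line at 0. The epithelial list lay at -1.81 between GFP+ and RFP+ cells as deposited, and the interferon-stimulated list at 2.19 between CTX-treated and untreated GFP+ cells.

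The comparison of CTX-treated GFP+ cells with untreated RFP+ cells combines drug and EMT state, which the design cannot separate here because RFP+ cells were not analysed after CTX. Epithelial genes lay below the RFP+ level after CTX as well, with 21 of 29 falling (1 rose and 25 fell when adjusted over the list alone, after scaling 25 fell; camera adjusted p = 3.18e-13, adjusted p = 0.843 with an estimated correlation). Cdh1 fell by 2.08 (SE 0.26, adjusted p = 0.00421), Epcam fell by 2.11 (SE 0.30, adjusted p = 0.00643), Lsr fell by 2.66 (SE 0.19, adjusted p = 9.86e-04) and Wfdc18 fell by 3.37 (SE 0.20, adjusted p = 5.35e-04). Of 21 mesenchymal genes 6 rose and 1 fell (10 and 1 when adjusted over the list alone, after scaling 8 rose and 1 fell; camera adjusted p = 0.00480, adjusted p = 0.843 with an estimated correlation). Fn1 rose by 1.23 (SE 0.32, adjusted p = 0.0440). Vim (0.68, adjusted p = 0.0735) and S100a4 (0.72, adjusted p = 0.154) did not pass as deposited. After scaling Vim was among the 8 mesenchymal genes that rose. Markers of other cells were examined here too. Of 9 stromal fibroblast markers, which overlap the mesenchymal list, 6 rose (7 when adjusted over the list alone, after scaling 7 rose), with a median of 1.66 (camera adjusted p = 1.34e-04, adjusted p = 0.787 with an estimated correlation, fry 0.0297). Of 4 leukocyte markers 3 rose (Cd68, Coro1a and Lyz2) and 1 fell (Cd14), as deposited and after scaling, genes named after their values were seen (camera adjusted p = 0.0931). Aldh1a1 rose by 2.26 (SE 0.18, adjusted p = 0.00119), S100a9 by 4.91 (SE 0.16, adjusted p = 5.80e-05) and the osteocalcin gene Bglap by 4.15 (SE 0.28, adjusted p = 9.17e-04). Cdkn1a had a log2 change of 3.04 (SE 0.88, adjusted p = 0.0587).

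Limma called 1437 genes higher and 784 lower in CTX-treated GFP+ than in RFP+ cells, 1959 and 2122 after scaling, and 1953 and 2350 after quantile normalization. Higher genes made up 64.7% of calls as deposited and 48.0% after median-ratio scaling. Higher and lower genes numbered 233 and 53 without RFP+ replicate 1, 400 and 304 without RFP+ replicate 2, 2788 and 2088 without untreated GFP+ replicate 1, 2787 and 2090 without untreated GFP+ replicate 2, 504 and 102 without CTX replicate 1, and 517 and 107 without CTX replicate 2. Averaging the CTX pair left 517 and 103. The naming rule selected 23 genes past the threshold, of which 22 passed after scaling. The other was Snora75. Of the same genes 16 and 17 passed without RFP+ replicate 1 or 2, 22 and 22 without untreated GFP+ replicate 1 or 2, 22 and 21 without CTX replicate 1 or 2, and 15 with the CTX pair averaged and values scaled.

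Whether the drug moved the genes of the EMT difference was examined by overlap and by correlation across genes, both of which share the untreated GFP+ samples. Of the 233 genes lower in GFP+ than in RFP+ cells, 62 were higher with CTX, where independent lists would share 28.6, and 2 were lower, against 1.10. As a group these 233 had a median change of 0.33 with CTX, against 0.25 for all genes. In CTX-treated GFP+ cells they still lay at a median of -1.02 against RFP+ cells. Of the 15 genes higher in GFP+ cells, 1 was higher with CTX, against 1.84, and 4 were lower, against 0.0711. After scaling, 64 of the 257 lower genes were higher with CTX, against 28.2, and 23 were lower, against 20.7. The 257 had a scaled median change of 0.16 with CTX, against -0.05 for all genes, and lay at -0.95 against RFP+ cells. Of the 133 higher genes 28 were higher with CTX, against 14.6, and 22 were lower, against 10.7, so the higher genes exceeded independent lists in both directions. Across 13080 genes, which are not independent replicates, the changes had a Pearson r of -0.105 and a covariance of -0.0334, where 100 simulations without any effect gave a mean r of -0.501 and covariance of -0.0523, a difference in covariance of 0.0189. With 1 untreated GFP+ sample in each comparison, r was 0.129 or 0.249 (covariance 0.0552 or 0.110), the opposite sign, but no value without effect was simulated for these splits. The replicate differences of RFP+ and untreated GFP+ cells correlated at 0.298. A shift shared in this way adds to the covariance of each split without any relation (0.0284 here, less than either split's covariance). The simulations do not contain it. They also gave every sample of a gene the same spread. The robust SD between replicates was 0.318 for untreated GFP+ and 0.0545 for CTX-treated cells. The covariance without effect may therefore lie below the simulated -0.0523, and the difference of 0.0189 is not a measure of a relation. The split values have no estimate of their spread and were not computed after scaling. The sign of the relation is left open for that reason, and part of each overlap may come from the shared samples.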

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

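The tests with the CTX pair averaged, those that combined median-ratio scaling with that averaging or with leaving out untreated GFP+ replicate 1, the one without accession-named and short RNA features, and the relation after scaling were chosen only after the results had been seen. Each group had 2 samples of unstated origin, the read totals were not available, and the spread was shared between groups that differed in it. When 1 sample of a group is left out, the lone sample is assumed to vary like the other groups. Counts are given as higher and lower genes for untreated GFP+ against RFP+, then CTX-treated against untreated GFP+, then CTX-treated GFP+ against RFP+, which were 15 and 233, 1607 and 62, 1437 and 784 as reported. Where a count or sign changed, the cause was not tested except where the setting itself, with fewer genes or samples or a stricter threshold, gives it.

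Counts became 133 and 257, 1437 and 1052, 1959 and 2122 with median-ratio scaling and 128 and 240, 1404 and 1477, 1953 and 2350 with quantile normalization. Without a filter on low values, which tests more genes, they were 1 and 2, 2109 and 56, 2197 and 670. With a mean FPKM of at least 5 they were 5 and 85, 540 and 18, 501 and 414. A pseudocount of 0.1 gave 13 and 180, 1155 and 43, 1174 and 676, and a pseudocount of 5 gave 18 and 291, 1849 and 67, 1666 and 871. No intensity trend gave 13 and 217, 1555 and 62, 1405 and 786, and robust moderation 33 and 349, 1774 and 77, 1516 and 928. With an absolute log2 change of at least 1 as well they were 14 and 209, 1014 and 26, 907 and 297. Models of only the 4 samples compared gave 7 and 105, 675 and 24, 2781 and 2084. Without accession-named and short RNA features they were 31 and 351, 1947 and 89, 1638 and 968.

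The CTX pair averaged to 1 sample gave 8 and 133, 424 and 8, 517 and 103. With scaling as well it gave 0 and 2, 45 and 0, 218 and 82. The counts of 0 there had 553 and 1014 genes at an unadjusted p under 0.05 in limma. Scaling without untreated GFP+ replicate 1 gave 13 and 73, 805 and 482, 2381 and 2866. Over leaving out each sample in turn, the counts in untreated GFP+ against RFP+ ranged from 0 to 161 higher and 1 to 4576 lower. In CTX-treated against untreated GFP+ they ranged from 431 to 5653 and 12 to 269, and in CTX-treated GFP+ against RFP+ from 233 to 2788 and 53 to 2090. The lowest counts of the first comparison came without an RFP+ sample (262 and 138 higher at an unadjusted p under 0.05 in limma where none passed) and the highest without untreated GFP+ replicate 2.

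Of the list tests 48 passed, against 0 with an estimated correlation (3 at an unadjusted p under 0.05 in camera), 10 in fry, and 42 to 55 under the other settings. The relation of the EMT and CTX changes across genes went from an r of -0.105 to 0.129 and 0.249 when the untreated GFP+ samples were divided between the comparisons, in either order, a division in which a shift shared by equally numbered samples raises r, and was -0.150 after scaling.

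For the single genes named, 1776 results kept their direction and side of the threshold, 495 lost the threshold, 83 gained it and 17 changed sign, none of them past the threshold as reported. The log2 change of Cdh1 with CTX became -0.13 with scaling, -0.11 with quantile normalization, -0.14 with scaling and the CTX pair averaged, and -0.27 with scaling without untreated GFP+ replicate 1. The difference of Mki67 between GFP+ and RFP+ cells became 0.13, 0.17, 0.13 and 0.27 in the same settings, and that of Cdkn1a 0.84 in the last. Over leaving out each sample in turn, the GFP+ to RFP+ differences ranged from -1.81 to 0.82 for Cdkn1a, -0.51 to 0.24 for Mki67 and -0.21 to 0.71 for Fn1. The CTX changes ranged from -0.15 to 0.55 for Cdh1, -0.53 to 0.37 for Epcam, -0.20 to 0.13 for Vim and -0.60 to 0.16 for Mki67.

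With the replicate number as a block, counts were 195 and 764, 2718 and 281, 2224 and 1303. The labels do not say that equally numbered samples belong together as a pair. The differences between replicates correlated across genes at 0.298 for RFP+ and untreated GFP+ cells. They correlated at -0.0364 for RFP+ and CTX-treated cells and at -0.107 for untreated and CTX-treated GFP+ cells. A replicate effect shared by all 3 groups is not seen in these values.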

Other observations

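All tests in this part were chosen only after the results had been seen. Genes of squamous differentiation, the program of skin-like epithelia, were among the largest increases in GFP+ cells with CTX, and the families below were picked for that reason, so their counts are descriptive. Of 29 measured genes of the epidermal differentiation cluster, a chromosomal region with cornified envelope and S100 genes, 22 rose as deposited and 21 after scaling (75.9% against 12.3% of all genes as deposited). Their median log2 change was 1.74 (1.60 scaled). The RefSeq table holds 70 protein-coding genes of this cluster. A gene counted as measured with an FPKM of at least 1 in at least 2 samples, which the 2 CTX samples alone can meet. The filter can therefore raise the share of measured members that rose, here and in the other families, the prolactin family included. The epidermal transcripts Lor, Flg and Flg2 did not reach the filter, at 0.0394, 0.177 and 0.00624 FPKM with CTX. Involucrin (Ivl) went from 0.172 ± 0.00119 to 5.99 ± 0.239 FPKM (log2 change 2.58, SE 0.14, adjusted p = 5.23e-04). Sprr1a went from 0.289 ± 0.208 to 20.2 ± 0.953 FPKM (log2 change 4.05, SE 0.18, adjusted p = 1.71e-04), and S100a4, S100a6 and S100a10 of the same region did not pass. Among keratins 8 of 13 rose (7 after scaling), including the stress keratin Krt16, from 7.08 ± 2.90 to 94.0 ± 1.68 FPKM (log2 change 3.60, SE 0.26, adjusted p = 0.00108). All 5 measured kallikrein-related peptidases rose (5 after scaling), such as Klk6 (log2 change 2.36, SE 0.18, adjusted p = 0.00108), and 12 of 13 clade B serpins (11 after scaling).

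Genes of the prolactin family, best known from the placenta, were also higher with CTX. Of 8 measured members 6 rose as deposited and 6 after scaling, with a median log2 change of 3.25 (3.02 scaled). Prl2c3 was at 562 and 564 FPKM with CTX and at 10.3 and 82.8 without (log2 change 4.20, SE 0.84, adjusted p = 0.0243). The members of these families are not independent, and near-identical copies such as the Prl2c and Sprr2 genes share reads, so values of single copies are uncertain.

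The squamous genes rose beside S100a9, Stfa3 and Cd68, which are abundant in leukocytes too, so material from other cells was weighed. Epidermal cells would bring transcripts of differentiated epidermis, but the highest of these, Krt10, was at 0.721 FPKM with CTX, against a median of 5.74 for the cluster genes that rose. Leukocytes would bring pan-leukocyte transcripts, and the highest of these, Coro1a, was at 1.11 FPKM beside Cd68 at 30.4. These values argue against epidermal cells and leukocytes as the main source, and the sort for GFP would also remove unlabelled cells. A small share of leukocytes stays open. Coro1a, Laptm5, Csf1r and Ptprc were at 0.658, 0, 0.0338 and 0.00321 FPKM in untreated GFP+ cells and at 1.11, 0.215, 0.195 and 0.0125 with CTX. Fcer1g and Itgam were lower with CTX, and Tyrobp and Emr1 were listed at 0. Squamous cells that lack Krt10 and reads shared between paralogs stay open. Whether tumour cells induced these genes or cells that already had them survived was not tested, and sequencing single GFP+ cells before and after CTX would tell these apart.

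Replicate 2 of both untreated populations differed from replicate 1 in the direction of the CTX change in 17 of 32 lists and in the opposite direction in 11, with scaled differences in RFP+ and GFP+ cells of 1.51 and 1.38 for interferon-stimulated genes, 0.62 and 0.81 for p53 targets, 0.63 and 0.57 for MHC class I, 0.47 and 0.45 for cytokines, 0.31 and 0.29 for matrix proteases, 0.33 and 0.22 for basal genes, -0.54 and -0.42 for ribosomal protein genes and -1.40 and -1.62 for cholesterol synthesis genes, while immediate early (0.91 and 1.48 against -0.32 with CTX), hypoxia (-0.51 and -0.44 against 0.20), YAP target (0.34 and 0.32 against -0.22) and NRF2 target genes (-0.37 and -0.29 against 1.05) moved opposite to CTX. A scale factor per library moves all genes alike, and the scaling had already removed it. The differences that remained in GFP+ cells, 1.38 for interferon-stimulated and -1.62 for cholesterol synthesis genes, argue against it as the whole cause. CTX-treated material would imply 1 share for every gene raised by CTX. In RFP+ and GFP+ cells interferon-stimulated genes implied 24.7% and 29.4% (lower quartiles 20.7% and 24.0%). The p53 targets implied 19.2% and 19.2% (quartiles 9.64% to 34.4% and 12.6% to 31.0%), which overlap these. NRF2 and glutathione genes implied -4.29% and -7.69% (upper quartiles 2.97% and 2.86%). For 20 genes of the epidermal differentiation cluster the medians were 0% and 0% (upper quartiles 1.86% and 0.0135%). The NRF2, glutathione and cluster values argue against 1 shared source. A shared batch or culture day of equally numbered samples cannot be told apart from separate shifts, since the labels give no date, and the replicate differences correlated at 0.315 across genes. Culture conditions such as cell density could therefore contribute to the CTX changes of lists that shifted the same way, among them the interferon, p53, MHC class I, cytokine, cholesterol, matrix protease, basal and ribosomal lists (scaled medians 1.88, 1.26, 0.99, 0.76, -1.35, 0.61, 0.48 and -0.56), and no biological explanation was tested.

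Epithelial genes in untreated GFP+ cells lay at similar fractions of the RFP+ level after scaling. Over 20 of the 29 measured genes, those at 10 FPKM or more in RFP+ cells, the median was 24.8%. With ratios averaged over the replicates, these 20 ran from 21.3% for Grhl2 to 38.2% for Jup. By ratios of group means, they ran from 21.5% for Cldn7 to 38.5% for Jup, and the other 9 from 12.5% for Ovol2 to 34.3% for Ovol1. If RFP+ cells among the sorted GFP+ cells were the whole source, all would share 1 ratio. The SD of the log2 ratios (0.28) was 2.38 times the noise between replicates. That noise came from ratios of equally numbered samples, which the labels do not pair. A shift shared by such samples cancels in these ratios, so the noise may be understated. Other pairings were not computed, and this measure alone does not decide the question. With CTX the fractions ran from 13.0% for Lsr to 119.9% for Dsp, and the SD was 5.92 times the noise. A share of RFP+ cells would hold every gene at or above that share. Fgf13, Fgf7 and Cited1, chosen after their values were seen, lay at 15.2%, 18.6% and 18.8% of the RFP+ level, and Ovol2 lower, at 12.5%. The limit moved with the replicate, with 18.9% and 12.7% for Fgf13, 17.5% and 19.85% for Fgf7, and 24.1% and 13.8% for Cited1. Only a share below such values stays open, without a firm limit, as does red to green switching shortly before the sort. Epithelial expression in EMT cells themselves was not tested, and staining single sorted cells for E-cadherin would tell it from a mixture.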
